A study of Mus musculus with 24 samples.

How the data were processed

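RNA of mouse brains was measured on 24 short-oligonucleotide expression arrays. The mice were adult males taken at the same clock time, either after 6 h of sleep deprivation by gentle handling that began at light onset, or undisturbed. The cells of interest were those expressing Homer1a, the short activity-induced form of a postsynaptic scaffold protein. Per the labels' protocols, brains were fixed by perfusion with formaldehyde and polyadenylated RNA was immunoprecipitated on anti-FLAG beads by mRNA tagging, in which a FLAG-tagged poly(A)-binding protein marks the RNA of chosen cells. The recovered RNA was amplified before hybridization. The labels name this amplification for the immunoprecipitated RNA only, and whether supernatant and whole-brain RNA were amplified in the same way is not given in the sources used here, so amplification can differ between pull-down and both references. Groups were set from the labels: pull-down after sleep deprivation (n = 6), pull-down control (n = 6), supernatant, the total RNA left after the pull-down (n = 4), whole brain after sleep deprivation (n = 4) and whole-brain control (n = 4), the last pair from unfixed total RNA. For supernatant 13 the title says sleep-deprived and the source field says control, so the 4 supernatants were used as 1 group and no sleep deprivation comparison was made in them. Arrays are named by group and by the number in their title. Supernatants are what the pull-downs left, but the labels tie no supernatant to a pull-down array, and all arrays were treated as independent.

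The authors deposited a log2 intensity per probe set and array, made with RMA (background correction, quantile normalization and summarization by probe set); per the submitters' processing notes the affy package was used. No version is given, nor whether all extracts were normalized in 1 batch. Within pull-down the array medians ranged from 4.37 to 5.70 and the SDs of an array's values from 1.61 to 2.34. Quantile normalization over these arrays would leave nearly equal distributions. The deposited values therefore still hold array-wide differences, which enter the comparisons of pull-down below. The values were used as deposited, with no further scaling, offset or filter on low levels. Of 45101 probe sets in the deposited table, 64 controls were left out and 45037 were tested. The array annotation, of 2016, gave exactly 1 gene symbol for 34945 of them, several for 932 and none for 9160, and 18193 genes had at least 1 probe set. No genome positions are given, because a 3′ probe set measures a transcript and the annotation used here was read for gene symbols only. Which Homer1 transcript each Homer1 probe set measures is not given in the sources used here. Arrays have no read depth. Their number limits the precision. The p-values of single probe sets and of permutations of arrays measure the spread between these samples. Those of gene lists (camera, below) take genes as units, and those of the overlap (Fisher's exact test, below) take probe sets. No array pair had identical values, and the highest correlation, between whole brain after sleep deprivation 20 and 19, was r = 0.991 across probe sets, which are not independent replicates.

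Models were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with default settings), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A probe set was called enriched when higher in pull-down than in supernatant and also than in whole brain, each at an adjusted p under 0.05 in 1 fit of all 24 arrays with 5 groups, and depleted when lower in both. Pull-down and whole brain were each the equal-weight mean of their sleep-deprived and control groups. The study's design names such a selection as a first step and a sleep deprivation comparison among the selected probe sets as a second, so sleep deprivation was tested within pull-down (6 against 6) and within whole brain (4 against 4), each on its own arrays, over the enriched probe sets and over all. The difference between these effects was an interaction contrast on the 20 arrays of both extracts, and the overlap of their calls was tested with Fisher's exact test. Whole brain was also compared with supernatant.

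Lists of genes were compared with all other genes by camera of the same package, on 1 probe set per gene, with its preset correlation of 0.01 and, as an alternative, with the correlation estimated from the arrays. Members past the threshold were counted with the adjustment over all probe sets and adjusted over the list alone. There were 27 lists: 12 of gene function, named in the results with their values, and 15 of cell type markers. For sleep deprivation, the mean change of each list was also tested by an exact permutation test of the arrays. The list of 4 genes that the study's authors named (Homer1, Ptgs2, Jph3 and Nptx2) was chosen on these samples and is not independent evidence. Homer1, Ptgs2 and Nptx2 also stand in the list of immediate early genes, Homer1 in that of the postsynaptic density and Jph3 in that of calcium handling. The cold-inducible genes were also chosen as a list, of which Cirbp alone is given.

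Genes were named by a rule, each by its probe set with the smallest p among those with a single symbol. For sleep deprivation these were the up to 15 genes with the largest rise and up to 10 with the largest fall among those past the threshold, or the 10 with the smallest p where fewer than 10 passed. For the enrichment they were the 15 genes with the largest smaller-of-both log2 difference and the 10 most depleted ones. The probe sets of the authors' 4 genes, and the list members with the smallest p, were named in addition. Groups, models, threshold, lists, this rule and the alternatives chosen beforehand were fixed before the data were examined.

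Alternatives chosen beforehand were a trended robust prior, array weights, quantile normalization of all arrays, centring of each array on its median, the probe sets above the median mean level alone, a minimum fold change of 1.5, selection against a single reference, contrasts fitted on their own arrays, 1 fit of all 24 arrays for sleep deprivation, the mean of all probe sets of a gene in lists, the estimated correlation, and leaving out each array in turn. Covariate fits, blocks and left-out array sets for the pull-downs were added after seeing the data. In simulated data without an effect, the highest count of enriched probe sets in 20 draws was 0. With known changes added to 100 of 45037 simulated probe sets, 15% of 2-fold and 83% of 4-fold changes were recovered for pull-down, 81% and 100% for whole brain, 46% and 95% for the enrichment, and 7% and 61% for the interaction. All simulated errors were independent, with no array-wide factor. In the real pull-downs 1 component held 54.3% of the residual variance, so these rates need not hold for them.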

Results

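Transcript levels were measured in 24 mouse brain RNA samples of 3 extracts: RNA pulled down from Homer1a-expressing cells (12 arrays, 6 after 6 h of sleep deprivation and 6 controls), the supernatants of pull-downs (4 arrays) and whole brain (8 arrays, 4 and 4). Values are log2 RMA intensities, with the mean ± SD for a group and ± SE for a difference. The median log2 value of an array was 4.98 ± 0.38 (SD, n = 12) in pull-down, with a range of 4.37 to 5.70, against 6.15 ± 0.05 (n = 4) in supernatant and 6.13 ± 0.07 (n = 8) in whole brain. The 18S ribosomal RNA control, which has no poly(A) tail, averaged 8.54 in pull-down with a range of 6.83 to 11.1, 14.29 ± 0.09 in supernatant and 13.85 ± 0.05 in whole brain. The 3′ minus 5′ log2 difference of Gapdh, a measure of how far reverse transcription and RNA length reach, was 4.92 ± 0.78 in pull-down, 2.43 ± 0.13 in supernatant and 2.75 ± 0.16 in whole brain. Within pull-down it was 5.01 ± 0.80 after sleep deprivation and 4.84 ± 0.83 in controls (n = 6 each), and 18S read 8.49 ± 1.55 and 8.59 ± 1.59. Pull-down arrays correlated with the mean of their extract at 0.971 ± 0.021, and pull-down control 11, the lowest, at 0.913.

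**Figure D1:**
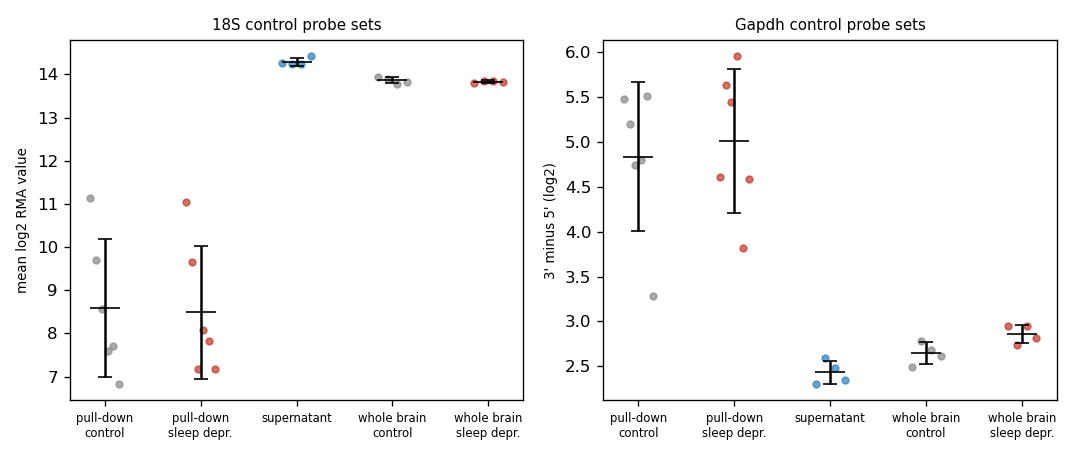
Control probe sets by array (points) in the 5 groups, with the mean ± SD: the mean log2 RMA intensity of 18S (one panel) and the log2 difference between the 3′ and 5′ probe sets of Gapdh (the other). The pull-down arrays spread from 6.83 to 11.1 for 18S, below all arrays of the other extracts.

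The comparison of pull-down with the other extracts asked which transcripts the Homer1a-expressing cells hold in excess. The Homer1 probe set 1436387_at was higher in pull-down than in whole brain by 1.42 ± 0.20 log2 units (SE, n = 12 and 8) and than in supernatant (n = 4) by 2.40. Probe sets 1437363_at (1.16 ± 0.17) and 1439662_at (1.38 ± 0.15) were higher than in whole brain too, whereas 1421768_a_at (−1.92 ± 0.27) and 1425710_a_at (−2.14 ± 0.29) of the same gene were lower. The remaining Homer1 probe set, 1425671_at, read −0.43 ± 0.34 against whole brain (adjusted p = 0.231) and was lower than in supernatant (−1.29, adjusted p = 0.00836). Against whole brain it read 0.063 after quantile normalization and 0.72 after centring, and it passed as lower with array weights (−0.63, adjusted p = 0.00251), without pull-down after sleep deprivation 1 and pull-down controls 3 and 11 (−0.58, 0.0151) and without the 2 arrays with the most 18S signal (−0.77, 0.0104). The prostaglandin synthase gene Ptgs2 (1417262_at) was higher by 1.22 ± 0.20 against whole brain and 1.76 against supernatant, while its probe set 1417263_at read 0.62 (adjusted p = 0.0220; 0.0721 without the 2 arrays with the most 18S signal, 0.0531 without whole brain after sleep deprivation 18 and 0.0581 without whole-brain control 24) and −0.12 (adjusted p = 0.724). The synaptic pentraxin gene Nptx2 was higher by 1.38 and 1.69 at 1420720_at and lower at 1449960_at (−0.69 and −1.10), where the difference from whole brain was 0.10 after quantile normalization and 0.47 after centring. The Jph3 probe sets, of a junctophilin that ties the endoplasmic reticulum to the plasma membrane, also went both ways, with 0.73 for 1443724_at and −1.25 for 1418161_at against whole brain, the latter −0.45 after quantile normalization (adjusted p = 0.108) and −0.096 after centring (0.815). The immediate early genes Nr4a2 (2.35 ± 0.16), Fos (2.07), Dusp1 (1.63 ± 0.19) and Rgs2 (1.42 ± 0.14) were higher in pull-down than in whole brain, and Per1 (−2.48 ± 0.24) was lower.

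Markers of non-neuronal cells were lower in pull-down than in whole brain. All 18 measured markers of endothelial cells and pericytes were lower, among them Slco1c1 (−3.39 ± 0.20), a transporter of the blood-brain barrier, Vtn (−3.23 ± 0.16), Cldn5 (−2.83 ± 0.17), a tight junction protein, and Flt1 (−2.52 ± 0.17). Of 18 astrocyte markers 16 were lower, with Mlc1 (−3.98 ± 0.32) and Aldoc (−3.27 ± 0.28) far below and Acsbg1 at −1.90 ± 0.14. Of 15 oligodendrocyte markers 13 were lower, including the myelin genes Mobp (−3.20 ± 0.21) and Mag (−2.78 ± 0.21), and all 15 microglia markers were lower, such as Aif1 (−3.20 ± 0.21) and the complement gene C1qa (−1.95 ± 0.15). Neuron markers went both ways, with 6 of 15 higher: the neuronal splicing factor Rbfox3 was higher by 1.45 ± 0.14, and the deubiquitinase Uchl1 read −3.79 ± 0.34. The median gene differed by −0.64 between pull-down and whole brain, and the lists were tested against all other genes. Endothelial cells and pericytes (adjusted p = 0.000101), oligodendrocytes (0.0128), astrocytes (0.0145) and microglia (0.0251) passed as lower. With an estimated correlation they did not, with adjusted p = 0.321, 0.321, 0.503 and 0.321 with an estimated correlation, in the same order. Against supernatant, where 18 of 18, 12 of 15, 15 of 18 and 13 of 15 of these markers were lower, none of the 4 lists passed with the preset correlation either (adjusted p = 0.0754, 0.271, 0.305 and 0.107). Markers of endothelial cells and pericytes, oligodendrocytes and astrocytes were also higher in whole brain than in supernatant (adjusted p = 0.000847, 0.0294 and 0.0294, each with adjusted p = 0.622 with an estimated correlation).

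Immediate early genes as a group were higher in pull-down than in whole brain, with 24 of 37 above, 17 past the threshold as higher and 11 as lower (adjusted p = 4.5e-07, and adjusted p = 0.281 with an estimated correlation). The authors' genes had 3 of 4 above (0.0106, and adjusted p = 0.321 with an estimated correlation), which is not independent evidence. Homer1, Ptgs2 and Nptx2 are members of both lists. For oxidative phosphorylation the median (−0.13) and the mean (−0.35) of 41 genes lay below 0 while the test called the list higher than other genes (0.0391, and adjusted p = 0.851 with an estimated correlation). That call turned to lower after quantile normalization (0.000581). Against supernatant, 24 of 37 immediate early genes (9.3e-05) and 28 of 41 oxidative phosphorylation genes (1.5e-05) were above, both with adjusted p = 0.842 with an estimated correlation. The other 20 lists did not pass against whole brain. All 12 markers of thalamic and all 17 of hypothalamic neurons were below whole brain (adjusted p = 0.0869 each), forebrain excitatory neurons and blood also had 0.0869, and choroid plexus and pituitary had 0.170. Adjusted p was 0.281 for chaperones, 0.353 for ribosomal proteins and for synaptic vesicles, 0.369 for the clock, 0.371 for neurons, 0.409 for the postsynaptic density and 0.444 for striatal neurons. It was 0.617 for glucocorticoid-responsive, glucose and calcium genes, interneurons and oligodendrocyte precursors, 0.731 for cholesterol synthesis and 0.743 for cerebellar neurons.

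In all, 3358 probe sets were higher in pull-down than in both references, and 29613 were lower. Both contrasts share the 12 pull-down arrays. With a different part of the pull-downs against each reference, 10 divisions gave 2839 to 3483 enriched probe sets (median 3012) and 24947 to 29542 depleted ones. The study's design gives 4728 enriched probe sets at a false discovery rate of 5%; which they are is not given in the sources used here. The gene with the largest measured difference was Fmn1 (1439397_at), a formin that assembles actin, at 9.61 ± 0.38 (SD, n = 12) in pull-down, 4.95 ± 0.65 (n = 8) in whole brain and 4.86 ± 0.37 (n = 4) in supernatant. That is a log2 difference of 4.66 ± 0.22 (SE) against whole brain (adjusted p = 2.4e-15) and 4.75 against supernatant (3.6e-13). It was followed by Lrrc6 (3.58 against whole brain), Mrpl44 (3.56 ± 0.16), a mitochondrial ribosomal protein, Dkc1 (3.51 ± 0.18), the pseudouridine synthase of small RNA-protein particles, Dmp1 (3.27), Cntn3 (3.26), Pus7l (3.67), Eif2a (3.10), Hivep3 (2.97), Rps25 (2.97 ± 0.31), Sarnp (2.95), Aplnr (2.94), Tex10 (2.94), the inducible heat shock gene Hspa1b (2.91 ± 0.22) and Entr1 (2.90). Fmn1, Lrrc6, Pus7l, Eif2a and Aplnr read below the array median in both references, and no background level was set, so the size and rank of their differences are not firm. Of the enriched probe sets 69.8% were of the kinds _at and _a_at, which are designed for 1 gene. These kinds hold 36082 and 4426 of the 45037 probe sets tested. Probe sets of the kinds _s_at and _x_at, which can bind transcripts of several genes, were enriched 4.29 times as often as those of the kind _at (17.7% and 26.4% against 5.22%), and several of the genes named here rest on such probe sets.

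By the smaller of both differences the most depleted gene was AY036118 (−4.97 against whole brain, −5.39 against supernatant). Against whole brain alone Ptgds (1423860_at), the prostaglandin D synthase of meninges and oligodendrocytes, had the largest difference of the 10 genes named, −5.52 ± 0.22 (SE). It read 5.35 ± 0.62 (SD, n = 12) in pull-down and 10.88 ± 0.16 (n = 8) in whole brain. Next were Mbp (−5.36 ± 0.26), the myelin basic protein, AY036118 (−4.97), the glycolytic gene Aldoa (−4.95), the nuclear long RNA Malat1 (−4.82 ± 0.42), Kirrel3 (−4.78), Kidins220 (−4.50), the glutamine synthetase gene Glul (−4.48), the desaturase gene Scd2 (−4.46) and Hnrnpab (−4.46). The values of Aldoa (1433604_x_at) and Malat1 (1427285_s_at) rest on kinds of probe set that can bind transcripts of several genes. The median probe set differed by −0.78 between pull-down and whole brain and by −0.85 between pull-down and supernatant as deposited. After quantile normalization these medians were 0.09 and 0.02, with 10045 enriched and 9384 depleted probe sets (3243 and 9239 shared with those above). After centring they were 0.37 and 0.32, with 17898 enriched and 6224 depleted.

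In whole brain, sleep deprivation was asked to show what 6 h awake changes across all cells. The activity-induced genes Arc (1418687_at, 1.22 ± 0.15, adjusted p = 0.0140), which acts at synapses, Egr2 (1427682_a_at, 1.14 ± 0.16, 0.0250) and Fos (1423100_at, 1.06 ± 0.12, 0.0115), both transcription factors, rose (SE, n = 4 and 4). For each, 4 of 4 sleep-deprived arrays lay above the control mean, without overlap between the groups. Fos went from 5.79 ± 0.21 to 6.85 ± 0.06 (SD). Homer1 rose by 0.85 ± 0.13 at 1436387_at (0.0406), from 8.65 ± 0.25 to 9.49 ± 0.09, and by 0.84 ± 0.13 at 1425671_at (0.0408). Its other probe sets read 0.46 ± 0.12 (1421768_a_at, 0.254), 0.17 (1437363_at), 0.15 (1425710_a_at) and 0.13 (1439662_at). Genes that glucocorticoids induce rose as well: Plin4 (1418595_at), a lipid droplet protein, by 1.48 ± 0.12 from 5.41 ± 0.12 to 6.89 ± 0.16 (0.000320), the kinase gene Sgk1 (1416041_at) by 1.16 ± 0.16 (0.0208), Zbtb16 (1419874_x_at) by 0.97 ± 0.12 (0.0140) and the leucine zipper gene Tsc22d3 (1420772_a_at) by 0.89 ± 0.12 (0.0202).

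Further rises in whole brain were those of Hif3a (1.10 ± 0.14), of the hypoxia-inducible factor family, Dio2 (1.05 ± 0.13), which makes active thyroid hormone, Zmym1 (1.00 ± 0.15) and the phagocytosis receptor Mertk (0.72 ± 0.11), with adjusted p of 0.0193, 0.0140, 0.0363 and 0.0408. Opalin (1435854_at), a myelin membrane protein, fell by 0.93 ± 0.13 (adjusted p = 0.0250), the transcription factor Creb5 by 0.81 ± 0.13 (0.0424) and the oestrogen receptor gene Esr1 by 0.79 ± 0.12 (0.0363). For each, 4 of 4 sleep-deprived arrays lay below the control mean. After quantile normalization Creb5 had 0.0501 and Esr1 0.113. In total 21 probe sets passed over all (16 higher, 5 lower) and 19 over the enriched ones (14 higher, 5 lower). Over all, the split was 40 higher and 8 lower after quantile normalization and 40 and 6 after centring. The count over all was 1 without whole brain after sleep deprivation 21 or 19, 13 without 18 and 10 without 20, and 6, 12 and 8 without controls 24, 22 and 25. Over the enriched ones it was 11 without sleep-deprived 21, 19 or 20 or control 24, 10 without control 25, and both counts were 0 in 1 fit of all 24 arrays, whose spread includes the pull-downs'. At an unadjusted p under 0.05 the balance was the opposite of that of the calls. Of 4926 such probe sets over all, 947 were higher and 3979 lower, where 2252 in total would be expected by chance. The median shift of all probe sets was −0.07 as deposited.

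By list, 29 of 37 immediate early genes were above control in whole brain, 3 past the threshold over all genes and 17 adjusted over the list alone (adjusted p = 7.3e-22, and adjusted p = 0.000692 with an estimated correlation). Besides those above, Dusp1 read 0.77 ± 0.12 (adjusted p = 0.0502) and Inhba 0.70 ± 0.12. Of 24 glucocorticoid-responsive genes, 23 were above, 4 past the threshold and 16 adjusted over the list alone (3.5e-32, and adjusted p = 0.00199 with an estimated correlation). Dusp1, Per1 and Errfi1 stand in both lists. Of 33 chaperones and genes of the unfolded protein response 28 were above, 0 past the threshold in limma and 4 adjusted over the list alone (2.1e-10, and adjusted p = 0.0279 with an estimated correlation). Among them Creld2 read 0.48 ± 0.11, Hspa5, the main chaperone of the endoplasmic reticulum, 0.48 ± 0.12 and Dnajb5 0.49 ± 0.13. By exact permutation of the arrays each of these lists had the smallest p the design allows, 0.0286, which was 0.154 after adjustment over the 27 lists.

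Other lists passed in whole brain only with the preset correlation, with 0 members past the threshold over all genes. The clock list had 16 of 22 above and 2 adjusted over the list alone (adjusted p = 0.000632, and adjusted p = 0.200 with an estimated correlation), with Per2 at 0.71 ± 0.13. Cholesterol synthesis had 19 of 20 below, such as Mvd (−0.35 ± 0.14) and Ebp (−0.30 ± 0.13), with 0.0196 (adjusted p = 0.323 with an estimated correlation). Calcium handling had 20 of 27 above at 0.00285 (adjusted p = 0.143 with an estimated correlation), oxidative phosphorylation 29 of 41 at 0.00265 (adjusted p = 0.580 with an estimated correlation) and glucose and glycogen metabolism 14 of 25 at 0.0283 (adjusted p = 0.427 with an estimated correlation), with the glucose transporter gene Slc2a1 at 0.51 ± 0.11. Markers of neurons had 11 of 15 above at 0.0131 (adjusted p = 0.323 with an estimated correlation), of interneurons 11 of 15 at 0.0136 (adjusted p = 0.309 with an estimated correlation) and of astrocytes 10 of 18 at 0.0332 (adjusted p = 0.200 with an estimated correlation). The authors' 4 genes were all above, 0 past the threshold by their list's probe sets and 1 adjusted over the list alone (0.00143, and adjusted p = 0.0679 with an estimated correlation), which is not independent evidence. Ptgs2 read 0.54 ± 0.15 (adjusted p = 0.302), Nptx2 0.30 ± 0.15 and the Jph3 probe sets 0.21 ± 0.13 and 0.10 ± 0.11. The other 15 lists had adjusted p from 0.141 (ribosomal proteins) to 0.727 (blood), and 12 passed, 3 of them with an estimated correlation. Without control 22 there were 7. The cold-inducible gene Cirbp read −0.87 ± 0.16 (adjusted p = 0.0935).

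In pull-down, the comparison asked how RNA pulled down from Homer1a-expressing cells differs after sleep deprivation. As Homer1a is activity-induced, the cells that express it can differ between the groups. The design cannot tell such a change from a response within the same cells. The immediate early genes Egr2 and Fos and the activity-induced genes Homer1 and Ptgs2 read higher after sleep deprivation, with no gene past the adjusted threshold. Egr2 (1427682_a_at) was at 9.63 ± 0.40 after sleep deprivation and 7.58 ± 1.06 in controls (SD, n = 6 and 6), a difference of 2.04 ± 0.40 (SE, adjusted p = 0.148). Ptgs2 (1417262_at) was at 7.48 ± 0.22 and 6.14 ± 0.62 (1.35 ± 0.28, 0.148), and Homer1 (1436387_at) at 11.10 ± 0.29 and 9.89 ± 0.55 (1.20 ± 0.27, 0.203), both without overlap between the groups. Fos (1423100_at) differed by 1.19 ± 0.38 (adjusted p = 0.920). Spry4 (0.98 ± 0.22, 0.207), an inhibitor of receptor tyrosine kinase signals, Gpt2 (1.14 ± 0.30, 0.469), a mitochondrial transaminase, Ccn4 (0.91 ± 0.25, 0.584) and Pkp2 (0.98 ± 0.28, 0.648) followed among the genes with the smallest p. Gadd45b (0.78 ± 0.23), Mkks (0.73 ± 0.22) and A230051N06Rik (−0.81 ± 0.25) had adjusted p of 0.894, 0.920 and 0.920. For each of these genes, 6 of 6 sleep-deprived arrays lay on that side of the control mean. The groups still overlapped for Egr2, Fos, Pkp2, Gadd45b and A230051N06Rik. For Fos, pull-down control 8 read 9.45, above the highest sleep-deprived array (9.44).

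**Figure D2:**
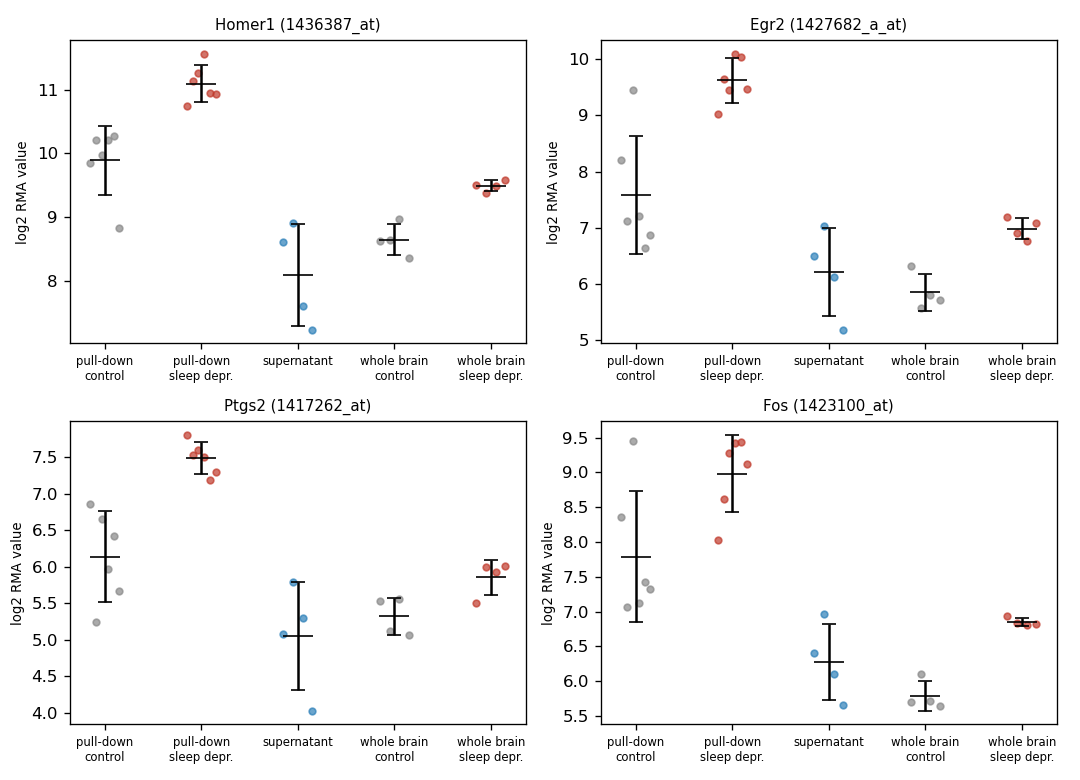
Log2 RMA intensity of Homer1 (1436387_at), Egr2 (1427682_a_at), Ptgs2 (1417262_at) and Fos (1423100_at) by array (points) in the 5 groups, with the mean ± SD. After sleep deprivation Homer1 averaged 11.10 in pull-down and 9.49 in whole brain, against 9.89 and 8.65 in controls.

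Other Homer1 probe sets in pull-down read 1.57 ± 0.52 (1425671_at), 1.14 ± 0.42 (1421768_a_at), 0.76 ± 0.43 (1425710_a_at), 0.39 ± 0.26 (1437363_at) and 0.36 ± 0.24 (1439662_at). Nptx2 read 0.79 ± 0.25 at 1420720_at (adjusted p = 0.920) and 0.03 ± 0.23 at 1449960_at, Ptgs2 0.76 ± 0.36 at 1417263_at, and Jph3 0.50 ± 0.23 at 1443724_at and 0.27 ± 0.49 at 1418161_at. Cirbp read −0.83 ± 0.30. Over the enriched probe sets limma called 0, with 86 at an unadjusted p under 0.05 (58 higher, 28 lower) where 168 would be expected by chance, and over all it called 0, with 430 (222 higher, 208 lower) where 2252 would be. Without pull-down control 8, Egr2 passed over the enriched probe sets (2.42, adjusted p = 0.00149). With array weights Homer1 (1436387_at, adjusted p = 0.0134), Ptgs2 (0.0173), Gpt2 (0.0173), Spry4 (0.0377) and Mkks (0.0428) passed, and in 1 fit of all 24 arrays Egr2 and Spry4 (0.00512 each), Ptgs2 (0.0191) and Homer1, Gpt2 and Ccn4 (0.0273 each) did. That fit pools the spread of pull-down with the smaller one of whole brain (median residual SD 0.503 and 0.183). Its p-values for pull-down therefore tend to be too small. Arrays with a title number of 7 or lower (4 sleep-deprived, 2 control) and those with a higher one (2 and 4) differed in 18S and in many probe sets. Within these parts the differences were 1.90 and 2.22 for Egr2, 1.56 and 1.06 for Ptgs2, 1.14 and 1.12 for Homer1 (1436387_at) and 1.13 and 1.45 for Fos, with 0.0667 as the smallest exact p a part allows.

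As groups, immediate early genes, chaperones and glucocorticoid-responsive genes were higher after sleep deprivation in pull-down, with 0 members past the threshold over all genes in limma for any list. Of 37 immediate early genes 32 were above control, 9 adjusted over the list alone (adjusted p = 5.1e-29, and adjusted p = 0.000985 with an estimated correlation), such as Fosl2 (1.22 ± 0.27), the phosphatase gene Dusp4 (1.12 ± 0.26) and Egr3 (0.85 ± 0.27). Of 33 chaperones 31 were above, 4 adjusted over the list alone (1.2e-20, and adjusted p = 0.00469 with an estimated correlation), with Hspa5 at 1.14 ± 0.30, Creld2 at 0.97 ± 0.24, Sdf2l1 at 0.84 ± 0.23 and Hspa1b at 0.84 ± 0.26. Of 24 glucocorticoid-responsive genes 20 were above, 0 adjusted over the list alone (6.5e-12, and adjusted p = 0.00469 with an estimated correlation), with Plin4 at 0.83 ± 0.37, Dusp1 at 0.73 ± 0.30, Mt2 at 0.66 ± 0.31 and Tsc22d3 at 0.65 ± 0.26. The authors' genes were above in 4 of 4, 2 adjusted over the list alone (9.3e-09, and adjusted p = 0.0217 with an estimated correlation), which is not independent evidence. Since Homer1, Ptgs2 and Nptx2 are also in the immediate early list, the results of both lists are not separate. By exact permutation of the arrays these 4 lists had p = 0.00216, the smallest the design allows, 0.0714, 0.0130 and 0.0281, and 0 lists passed after adjustment (immediate early genes 0.0584).

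**Figure D3:**
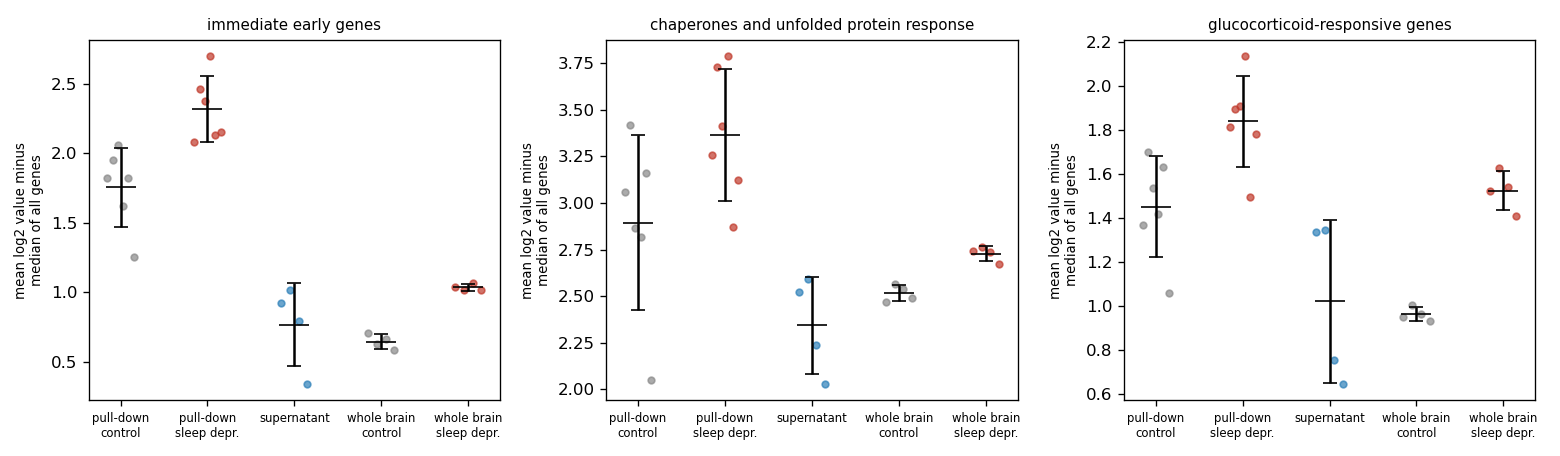
Mean log2 RMA intensity of the members of 3 lists (immediate early genes, chaperones and unfolded protein response, glucocorticoid-responsive genes) minus the median of all genes of the array, by array (points) in the 5 groups, with the mean ± SD. In pull-down the mean of these scores was higher after sleep deprivation by 0.56 for immediate early genes, 0.47 for chaperones and 0.39 for glucocorticoid-responsive genes.

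Within the parts of lower and higher title numbers, the scores of immediate early genes differed by 0.52 and 0.46 (0.56 over all pull-downs), those of chaperones by 0.31 and 0.27 (0.47 over all) and those of glucocorticoid-responsive genes by 0.41 and 0.23 (0.39 over all). With that division as a block their adjusted p by camera with the preset correlation was 1.5e-17, 2.1e-08 and 1.2e-07, and 0.000882 for the authors' genes. Ribosomal proteins (24 of 30 above, adjusted p = 1.7e-05, and adjusted p = 0.290 with an estimated correlation) differed by 0.09 and 0.06 within the parts, and had 0.374 with the block. Oxidative phosphorylation (30 of 41 above, 0.00339, and adjusted p = 0.815 with an estimated correlation) differed by 0.08 and −0.07 and was lower with the block (0.819). The clock list (15 of 22 above, 0.0176, and adjusted p = 0.538 with an estimated correlation) had 0.879 with the block, with Per2 at 0.92 ± 0.40. Choroid plexus markers (12 of 13 below, 0.0176, and adjusted p = 0.695 with an estimated correlation) had 0.234. The other 19 lists had adjusted p from 0.0572 (postsynaptic density) to 0.884 (oligodendrocytes), and of the 8 that passed 4 held with an estimated correlation. The number of lists that passed was 16 without pull-down control 3, 15 without sleep-deprived 10, 14 without sleep-deprived 12 or control 4, and 5 without sleep-deprived 6.

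Whether the response differed between the extracts was tested directly. Of the 21 probe sets called in whole brain, 20 had the same direction in pull-down, with a median size of 0.65 there and 0.93 in whole brain, and 11 had an unadjusted p under 0.05 in pull-down. These probe sets were chosen for passing in whole brain, which favours larger sizes in that extract. Their median sizes therefore cannot tell which extract responded more. For the interaction limma called 0 of all probe sets, with 152 at an unadjusted p under 0.05 (90 higher, 62 lower in pull-down). Chaperones (26 of 33 more positive in pull-down, adjusted p = 4.2e-05, and adjusted p = 0.265 with an estimated correlation) and immediate early genes (27 of 37, 0.00350, and adjusted p = 0.295 with an estimated correlation) differed upward. The authors' genes (0.00350, and adjusted p = 0.295 with an estimated correlation) and ribosomal proteins (24 of 30, 0.0143, and adjusted p = 0.935 with an estimated correlation) did too. Homer1, Ptgs2 and Nptx2 are members of both the authors' and the immediate early list. Glucocorticoid-responsive genes differed downward (16 of 24, 0.000634, and adjusted p = 0.265 with an estimated correlation). Immediate early genes did not pass after quantile normalization (0.824) or centring (0.129), nor did the authors' genes (0.108 and 0.129), and ribosomal proteins did not after centring (0.256). Without pull-down control 11 adjusted p was 0.190 for immediate early genes and for the authors' genes, 0.121 for chaperones and 0.691 for ribosomal proteins. The overlap of calls at the adjusted threshold was 0 in limma. At an unadjusted p under 0.01, 52 probe sets were higher in pull-down and 320 in whole brain, with 22 in both where 0.369 would be expected (Fisher's exact p = 5.8e-34). Of 33 and 975 lower ones, 9 were in both where 0.714 would be expected (2.4e-08), and probe sets are not independent. Across 18193 genes, which are not independent replicates, the changes of both extracts correlated at r = 0.377 and rho = 0.367. The median residual SD between arrays of a group was 0.503 in pull-down and 0.183 in whole brain.

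Whole brain and supernatant, both total RNA, differ in perfusion, fixation and the pull-down step, and their comparison gives the background of handling. Oxidative phosphorylation genes were higher in whole brain in 39 of 41, 23 past the threshold (adjusted p = 1.1e-10, and adjusted p = 0.622 with an estimated correlation). So were markers of endothelial cells and pericytes in 14 of 18, 10 past the threshold (0.000847), and of neurons in 14 of 15, 6 past it (0.00103). Ribosomal proteins (25 of 30, 0.0147), glucose metabolism (19 of 25, 0.0161), astrocytes (14 of 18, 0.0294) and oligodendrocytes (13 of 15, 0.0294) followed, each of these lists with adjusted p = 0.622 with an estimated correlation. Chaperones were higher in 25 of 33 (0.0314, and adjusted p = 0.748 with an estimated correlation). In total 4913 probe sets differed, 4006 higher in whole brain and 907 lower, with a median shift of −0.03. With array weights the split was 7860 and 5983, and after quantile normalization it was 5153 and 4329 and 3 of these 8 lists passed. Without supernatant 13 the count was 3022.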

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

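The tests of probe set kind, of Gapdh ends, of array medians, of the spread ratio, of a missing response, of a single array and of RNA breakage, the splits for the sleep deprivation lists, the fits with residual components, 18S or title number as a covariate or block, and the relations with title number were chosen after the result was seen; the others were planned.

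In single arrays, 11 of 157 groups held a value far from the rest of its group, where chance gives about 7.85. The Gapdh 3′ minus 5′ value was 3.29 in pull-down control 11, with the others between 4.74 and 5.51. The 18S value was 14.42 in supernatant 13, with the others between 14.23 and 14.26. The correlation with the mean of the extract was 0.952 in pull-down after sleep deprivation 1 (others 0.975 to 0.985) and 0.913 in pull-down control 11 (others 0.966 to 0.987). Homer1 at 1425710_a_at read 8.27 in pull-down after sleep deprivation 1 (others 5.80 to 6.59) and 7.51 in pull-down control 3 (others 4.98 to 5.69), and at 1436387_at it read 8.82 in pull-down control 11 (others 9.85 to 10.28). Ptgs2 read 5.50 in whole brain after sleep deprivation 21 (others 5.93 to 6.01), and Fos 6.11 in whole-brain control 24 (others 5.64 to 5.71). The score of choroid plexus markers was −0.95 in pull-down after sleep deprivation 1 (others −0.52 to −0.28) and −0.80 in pull-down control 3 (others −0.38 to −0.20).

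The effect of sleep deprivation differed between pull-down and whole brain for 5 lists by the interaction test with the preset correlation: immediate early genes (adjusted p = 0.00350), the authors' genes (0.00350), chaperones (4.2e-05), glucocorticoid-responsive genes (0.000634) and ribosomal proteins (0.0143). With an estimated correlation the adjusted p were 0.295, 0.295, 0.265, 0.265 and 0.935. Of 100 splits of the arrays, 67 gave at least 5 lists and the highest other gave 19, so chance is not excluded for their number. For single probe sets the interaction gave 0 calls in limma (152 at an unadjusted p under 0.05), as did all 100 splits, the highest other being 0. Control probe sets outside the comparisons also differed between extracts: the Gapdh 3′ minus 5′ value averaged 4.92 in pull-down and 2.75 in whole brain, and that of actin 0.49 and −0.43.

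The first pattern is that most of the transcriptome read lower in pull-down while a smaller part read higher. Of 100 splits of the arrays 1, the real one, gave as many enriched (3358, highest other 0) or depleted probe sets (29613, highest other 0). The other splits mix the extracts, which widens the spread within groups. This argues against chance for a difference between the extracts, and says nothing on its cause or on single probe sets. Of the enriched probe sets 69.8% are of the kinds _at and _a_at, but these kinds hold 36082 and 4426 of the 45037 tested. Their majority was thus given by the array and decides nothing about binding of several genes' transcripts. As designed for 1 gene, the 5.22% of _at probe sets that were enriched are not expected to come from such binding. It may account for part of the _s_at and _x_at probe sets, because these were enriched 4.29 times as often. A difference in the level of whole arrays is argued against for the enriched part, since the highest pull-down median minus the lowest of the other arrays was −0.34 and a lower level works against higher calls; it stays open for the depleted part, since centring raises every pull-down value of an array alike, so that the 21.02% of depleted and 100% of enriched probe sets still called after it decide nothing by themselves, whatever the bounds set beforehand. Recovery of 3′ ends alone stays open: every pull-down array exceeded every whole-brain array in Gapdh 3′ minus 5′, by at least 0.34, while the 63.4% of other probe sets of the enriched genes that were depleted is close to the 65.8% of all probe sets, so that test cannot tell.

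The second pattern is that no probe set passed for sleep deprivation in pull-down (limma 0 over the enriched and 0 over all, with 86 and 430 at an unadjusted p under 0.05), a count that all 100 of 100 splits reached in both cases, with 2 and 16772 as the highest others. A lack of response in the pulled-down RNA stays open, since 20 of 21 whole-brain calls had the same direction in pull-down but total RNA carried over would give that too, and the larger spread between pull-down arrays is a candidate explanation, with a median residual SD 2.75 times that of whole brain. Carry-over itself was not decided: 0 probe sets passed without the 2 arrays with the most 18S signal. In simulated pull-downs 15% of 2-fold changes were recovered even with all arrays, and those simulations held no array-wide factor. The bound set beforehand therefore decides nothing. With 18S as a covariate 1 probe set passed, Homer1 at 1425671_at (adjusted p = 0.0479). The split with 16772 calls points to a structure of the samples: it parted title numbers 1 to 7 (4 of 6 sleep-deprived, mean 18S 9.46) from 8 to 13 (mean 18S 7.61), and the first residual component (54.3% of the variance) went with title number at r = 0.806 (permutation p = 0.00203, adjusted 0.00406) and rho = 0.851 (0.00083, adjusted 0.00332), r = 0.880 without the 2 farthest arrays. With that division as a block limma called 0 over both sets, and with 2 residual components it called 8 over all, a count that 62 of 100 splits reached (highest other 28120), so chance is not excluded for those 8.

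The third pattern is that immediate early, chaperone and glucocorticoid-responsive genes were higher after sleep deprivation in pull-down, and a single array as the source is argued against, since at least 77.1% of each list's mean change was left without any 1 array. RNA breakage that differs between the groups stays open, as a Gapdh difference of 0.17 with an SD of 0.78 (exact permutation p = 0.738) neither shows nor excludes it. For the number of lists chance is not excluded: 57 of 100 splits gave 8 or more, with 19 as the highest other, so the preset correlation alone is no evidence here. The structure by title number may add to the pattern, as 4 of the 6 arrays in the lower part were sleep-deprived. The chaperone scores differed by 0.31 and 0.27 within the parts against 0.47 over all. With that block these lists passed by camera with the preset correlation (adjusted p = 1.5e-17, 2.1e-08 and 1.2e-07). For the reason just given, that is no evidence against this structure. The highest adjusted p over all their alternatives was 0.00469, with an estimated correlation. A response of the Homer1a-expressing cells to sleep deprivation stays among the open explanations, with 0 lists past an exact permutation test after adjustment. The design cannot tell such a response from a change in which cells express Homer1a.

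Further relations with title number were among 4 computed over the 12 pull-down arrays with 100000 permutations. For 18S r was −0.871 (permutation p = 0.00013, adjusted 0.00052), rho −0.809 (0.00216, adjusted 0.00432) and r −0.857 without pull-down after sleep deprivation 1 and control 13. For the array median r was 0.533 (0.0755, adjusted 0.101) and rho 0.623 (0.0343, adjusted 0.0457), and for Gapdh 3′ minus 5′ r was −0.486 (0.109, adjusted 0.109) and rho −0.483 (0.113, adjusted 0.113). What the title numbers stand for is not given in the sources used here.

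In whole brain, 1 of the 35 splits, the real one, gave as many calls over all probe sets (21, highest other 1) and over the enriched ones (19, highest other 1). Chance is argued against for these counts but not excluded. A share of 1 of 35 is the smallest possible, and no adjustment over the split tests was made. For the number of lists chance is not argued against, since 2 of 35 splits gave at least 12 (highest other 13). The difference between whole brain and supernatant (4913 probe sets, highest other 3) was reached by 1 of 100 splits. Here too the other splits mix the extracts, so chance is argued against only for a difference between them. Chance is not excluded for the number of lists there (33 of 100 splits, real 8, highest other 14), in pull-down against whole brain (49 of 100, real 7, highest other 16) or in pull-down against supernatant (95 of 100, real 2, highest other 18).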

How the results depend on the processing

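The covariate and block fits and the left-out sets of pull-down arrays were chosen after seeing the data; the other alternatives were planned. Over all alternatives, 260 of the counts stayed within 1.5 times the reported one and 64 moved; lists kept their side of the threshold in 626 cases, lost it in 127 and reversed in 5. Named probe sets kept theirs in 2665, gained it in 41, lost it in 114 and reversed in 12. Immediate early, chaperone and glucocorticoid-responsive lists stayed higher and past the threshold for sleep deprivation in both extracts under each alternative run for camera. By exact permutation 0 lists passed after adjustment in either extract. For immediate early genes that failure decides little, since their exact permutation p was the smallest the arrays allow. By exact permutation test it was 0.00216 in pull-down (adjusted 0.0584) and 0.0286 in whole brain (adjusted 0.154). Chaperones and glucocorticoid-responsive genes also reached the smallest exact permutation p in whole brain. In pull-down they did not, with exact permutation p = 0.0714 and 0.0130 (adjusted 0.482 and 0.175). Their failure there is thus not set by the smallest possible p alone. No paired analysis was possible because the groups share fewer than 2 numbers. Pull-down arrays had lower medians than the others and no background level was set, which limits what they show of weakly expressed genes. Where no reason is given, the cause was not tested. Adjusted p are given for lists, log2 differences for genes; PD is pull-down, WB whole brain.

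With quantile normalization 10045 probe sets were enriched and 9384 depleted, WB calls were 48 over all, and WB against supernatant gave 9482. Lists past the threshold were 5 in PD, 7 in WB, 6 in PD against supernatant, 14 in PD against WB, 3 in WB against supernatant and 3 for the difference, where immediate early (0.824) and the authors' genes (0.108) lost it. The other lists that lost it were clock (0.456), oxidative phosphorylation (0.612) and choroid plexus (0.108) in PD. In WB they were glucose (0.728), oxidative phosphorylation (0.789), calcium (0.204), neurons (0.641), interneurons (0.138) and astrocytes (0.789). In PD against WB oxidative phosphorylation turned to lower (0.000581), and Homer1 1425671_at (0.063) and Nptx2 1449960_at (0.10) turned to higher. Centring gave 17898 enriched, 6224 depleted and 46 WB calls over all, 8 lists in PD against supernatant and 2 for the difference (immediate early and authors' genes 0.129, ribosomal proteins 0.256), with the clock in PD at 0.111, Homer1 1425671_at at 0.72 and Nptx2 1449960_at at 0.47 in PD against WB. Scaling moves every value of an array, which shifts the median of pull-down against the others.

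The trended robust prior gave 40 WB calls over the enriched and 62 over all. Array weights gave 7 PD calls over the enriched and 2 over all, and 13843 in WB against supernatant (7860 higher, 5983 lower). The probe sets above the median level gave 13357 depleted, since fewer were tested, and WB calls of 29 and 57. A single fit of all 24 arrays, which pools the spread of extracts, gave 10 and 3 PD calls and 0 and 0 in WB. The overlap between extracts at an unadjusted p under 0.01 was 31.

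With an estimated correlation, lists past the threshold were 4 in PD, 3 in WB, and 0 in PD against supernatant, 0 in PD against WB, 0 in WB against supernatant and 0 for the difference. In PD clock (0.538), oxidative phosphorylation (0.815), ribosomal proteins (0.290) and choroid plexus (0.695) lost it. In WB the authors' genes (0.0679), clock (0.200), cholesterol (0.323), glucose (0.427), oxidative phosphorylation (0.580), calcium (0.143), neurons (0.323), interneurons (0.309) and astrocytes (0.200) did. With the mean of all probe sets of a gene, clock (0.161) and choroid plexus (0.0982) in PD and astrocytes in WB (0.0519) lost it, PD against supernatant had 7 lists, and oxidative phosphorylation in PD against WB turned to lower (0.913).

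For PD, 2 residual components gave 11 calls over the enriched and 8 over all, with quantile normalization 8 and 7, and the 18S covariate gave 1 over all. The title number as a covariate turned Jph3 1418161_at to −0.041, and the block to −0.16. With the block, clock (0.879), ribosomal proteins (0.374) and choroid plexus (0.234) lost the threshold and oxidative phosphorylation turned to lower (0.819). Without the 3 arrays that stand apart (sleep-deprived 1, controls 3 and 11), 4 lists passed, with clock at 0.630, ribosomal proteins at 0.0576, choroid plexus at 0.0614 and oxidative phosphorylation turned to lower (0.420).

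Leaving out each PD array in turn, calls ranged from 0 to 2 (without control 8) over the enriched and from 0 to 1 (without control 8) over all. Lists in PD ranged from 5 (without sleep-deprived 6) to 16 (without control 3) and lists of the difference from 3 (without sleep-deprived 1) to 8 (without control 3). In PD the clock ranged from 0.00300 (without control 4) to 0.670 (without control 11), and was above 0.05 also without sleep-deprived 1 (0.198), 3 (0.0600) or 6 (0.102) or control 8 (0.0587). Oxidative phosphorylation ranged from 1.5e-05 (without control 4) to 0.670 and lower (without control 11), with 0.141 and 0.133 without sleep-deprived 3 and 6. Ribosomal proteins ranged from 6.1e-07 (without control 4) to 0.0701 (without control 11). Choroid plexus ranged from 0.00466 (without control 3) to 0.182 (without sleep-deprived 1), with 0.102 without sleep-deprived 6 and 0.0730 and 0.0892 without controls 8 and 11. Jph3 1418161_at ranged from −0.11 (without sleep-deprived 1) to 0.65 (without control 3) and Nptx2 1449960_at from −0.035 (without sleep-deprived 1) to 0.11 (without control 13).

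In WB, calls ranged from 10 (without control 25) to 19 (without control 22) over the enriched and from 1 (without sleep-deprived 21 or 19) to 16 (without control 23) over all, and lists from 7 (without control 22) to 14 (without control 23). Cholesterol ranged from 0.00467 (without sleep-deprived 21) to 0.109 (without control 25), with 0.0709, 0.0730 and 0.0566 without sleep-deprived 19 and 20 and control 24. Glucose ranged from 0.00709 (without control 23) to 0.290 (without sleep-deprived 21), with 0.174 and 0.0875 without controls 22 and 25. Oxidative phosphorylation ranged from 0.000373 (without control 23) to 0.180 (without control 22), with 0.0956 without sleep-deprived 21. Neurons ranged from 0.00182 (without control 23) to 0.140 (without control 22), interneurons from 0.00303 (without control 25) to 0.0995 (without control 22) and astrocytes from 0.0178 (without sleep-deprived 20) to 0.165 (without sleep-deprived 18), with 0.132 without control 22. WB against supernatant ranged from 3022 (without supernatant 13) to 4324 (without WB after sleep deprivation 19).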

Other observations

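The supernatants entered no sleep deprivation comparison, since the labels of supernatant 13 conflict, and their list scores (the mean log2 level of a list minus the median of all genes of the array) are given by array as values only. For glucocorticoid-responsive genes the score was 1.34 in supernatant 15, 1.34 in 14, 0.76 in 16 and 0.64 in 13. For immediate early genes it was 0.92, 1.01, 0.79 and 0.34 in the same order, and for chaperones 2.52, 2.59, 2.24 and 2.03. The condition of these arrays was not inferred from the values.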
